A study of Homo sapiens with 84 samples.

How the data were processed

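ATAC-seq was analysed in 78 libraries of 9 triple-negative breast cancer cell lines. Per the labels' protocols, cells were held in medium with 2% FBS, collected 24 hours after the last treatment and put through Omni-ATAC, a variant of ATAC-seq with a detergent wash that lowers mitochondrial reads, with 50000 cells in each transposition. Tazemetostat was started on day -5, with cells passaged on days -3 and -1 and ipatasertib added on day 0, as the labels describe for MDA-MB-468. The same schedule is taken for the other lines. The labels list 84 samples; the 6 of HCC1806 were not analysed here. Groups are cell line and treatment, as the labels give them, with 3 replicates each; no label says whether these came from separate cultures.

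The authors deposited a table of read counts per peak, in whole numbers and not normalised, for 861439 peaks shared by all libraries, and a table that assigns each peak to 1 gene with its genomic class and its distance to the TSS. Per the submitters' processing notes, peaks were called with MACS2 and reads counted with featureCounts on hg38. Their versions, the aligner, the removal of duplicate reads and the shift of read ends to the Tn5 cut site are not given in the sources used here. Counting reads over whole peaks, which are wide against such a shift, makes the totals insensitive to a shift of a few bp, while removal of duplicates would lower counts at dense sites. One shared peak set lets lines be compared at the same sites, but 61 peaks carry no gene symbol and were left out of gene sums. A peak is tied to the gene of the nearest TSS, which need not be the gene it regulates. Of 25871 gene IDs, 25573 (98.8%) matched the RefSeq gene table, from which the gene types were taken. Coordinates are those of the deposited table (hg38).

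Libraries held 12292571 to 21459284 counts in peaks. Within each line, peaks were kept by filterByExpr with a minimum count of 10 and tested with the edgeR 4.0.16 quasi-likelihood test (TMM scaling, 1 mean for each treatment, robust fit) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 folds of at least 1 were counted beside all changes. Gene values are sums of the counts of peaks within 10 kb of the TSS (24455 genes with a symbol). For comparisons across lines, the counts of the 3 replicates were summed for each line and treatment and tested with the line as block, so that the spread is that between lines. Non-additive responses were tested as combination minus tazemetostat minus ipatasertib plus DMSO on the log2 scale. Differences in the response between lines were tested with an F test of line by treatment on single libraries. SE values are the log2 fold divided by the square root of the F value that corresponds to the p-value of the same test. Where that p-value was too small to convert, the F value of the test itself was used. Promoter shares are counts within 1000 bp of a TSS as a percentage of all counts, compared with exact sign-flip tests over lines.

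Gene lists (17 of them) covered markers of luminal, basal and mesenchymal cells, FOXO targets, Polycomb (PRC2) developmental targets, mammary involution and gp130-STAT3, the BCL2 family, the cell cycle, interferon response and antigen presentation, SREBP targets, AP-1 and ERK feedback, receptor tyrosine kinases, YAP/TEAD targets, immune and endothelial markers, the drug targets with their pathways, and housekeeping genes. They were tested with camera (limma 3.58.1; preset correlation of 0.01, and estimated) and fry, and their medians set against 10000 random lists matched in 50 bins of mean accessibility. Named genes are a panel of 20 lineage and pathway genes, of which 18 are reported. Added to it are the 8 genes with the largest rise and the 8 with the largest fall across lines (5 and 5 for each single agent), and the 2 and 2 largest within a line, with a mean log2 CPM of at least 2. For each list up to 4 passing members were named, or the largest where none passed. Genes named across lines also had the same direction in at least 8 of the 9 lines (4 of 4 for single agents), those within a line no overlap of replicates, and all were protein-coding or had a given symbol. Named peaks are the 3 and 3 largest across lines and the 1 and 1 largest in each line, among changed peaks with a mean log2 CPM of at least 2. Those across lines also had the same direction in at least 8 of the 9 lines, those within a line no overlap of replicates. Not every gene and peak chosen by these rules is reported. Lists, rules, tests and the main alternatives were fixed before the data were examined; the rule of 8 lines was set for 10 lines, HCC1806 among them, and applied to 9.

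Alternatives were DESeq2 1.42.0, size factors, total counts and abundance-trended (loess, span 0.3) offsets, no filter and a minimum count of 30, gene windows of 1 kb and 50 kb, fits of the compared groups alone, the replicate number as a block, and leaving out each replicate or line. Shared controls were simulated 20 times with unchanged groups. Other splits of the samples were fitted on random subsets of 5000 genes (3000 for differences between lines) or 10000 peaks (5000 across lines). The fits were tested on simulated counts drawn from the means and library sizes of the real libraries. At each fold 100 genes or peaks were changed. For the combination across 9 lines (23446 genes), 92% of genes changed 1.5-fold and 11% of genes changed 1.2-fold were recovered, and 8.04% of the calls were false. In BT-20 (50000 peaks), 62% of peaks changed 2-fold and 30% of those changed 1.5-fold were recovered, with 3.16% false calls. Motif content was not analysed here, since no genome sequence was used.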

Results

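Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in 9 established cell lines of triple-negative breast cancer (TNBC), the breast cancers that lack the oestrogen and progesterone receptors and HER2 amplification. The series asks how open chromatin in these lines responds to tazemetostat, to ipatasertib and to both together. Tazemetostat inhibits EZH2, the catalytic subunit of the Polycomb repressive complex PRC2, which methylates histone H3 at silenced genes. Ipatasertib inhibits the AKT kinases, which carry growth factor signals downstream of PI3K. MDA-MB-468, MDA-MB-231, SUM-149PT and SUM-159PT had 4 groups each, given DMSO, tazemetostat, ipatasertib or the combination. BT-20, BT-549, HCC1143, HCC1395 and HCC1937 had DMSO and the combination. Each agent was used at 5 uM. As described for MDA-MB-468, tazemetostat was given from day -5 and ipatasertib from day 0 for the last 24 hours, so a comparison of the single agents compares targets and lengths of exposure at once. The 78 libraries formed 26 groups of 3 and held 12292571 to 21459284 counts in peaks each, over 861439 peaks. In 76 of 78 pairs of replicate libraries the counts differed by less than sampling noise (median ratio of observed to sampling variance 0.850). The group means below therefore carry no SD. Comparisons across lines sum the 3 libraries of a group to 1 sample. Fits within a line and the F test between lines use the 3 as single libraries, so their p-values cover counting error only. In the comparisons across lines the line is the unit of replication and the spread is that between lines. The pairs above sampling noise both held HCC1395 DMSO replicate 3 (ratios of 1.62 and 1.66). Fitted as a mixture of the DMSO profiles of the other 8 lines, its counts gave BT-20 a share of 10.3%, the cause of which is open.

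The first question was which genes change in accessibility with the combination in TNBC lines in general. Chromatin within 10 kb of the TSS of A2M, which encodes a secreted protease inhibitor, rose by 1.47 ± 0.29 on the log2 scale (± SE, n = 9 lines). It did so in 9 of 9 lines, for example from 3.78 to 27.2 CPM (counts scaled to library totals) in MDA-MB-468. ZFHX3, a homeobox transcription factor (1.36 ± 0.23), CECR2, a bromodomain protein of chromatin remodelling complexes (1.33 ± 0.21), and PROX1, the homeobox factor of lymphatic endothelium (1.31 ± 0.23), also rose in 9 of 9 lines. So did CDH20, a cadherin (1.29 ± 0.18), and CALCR, the calcitonin receptor (1.28 ± 0.24). FOLH1, which encodes prostate-specific membrane antigen (1.29 ± 0.25), and NAP1L2, a nucleosome assembly protein of neurons (1.28 ± 0.25), rose in 8 of 9 lines each. The largest falls lay at C19orf71 (-0.95 ± 0.16), at the readthrough locus RPL36A-HNRNPH2 (-0.95 ± 0.13), at GTF3C2, a subunit of an RNA polymerase III initiation factor (-0.93 ± 0.14), and at GNL3, a nucleolar GTPase (-0.87 ± 0.15). MCM4, a subunit of the replicative helicase (-0.78 ± 0.14), GTSE1, a mitotic regulator (-0.73 ± 0.17), TMEM87A (-0.72 ± 0.15) and IL4I1, a secreted amino acid oxidase (-0.72 ± 0.17), fell too, each in 9 of 9 lines. Adjusted p for these genes lay between 0.00283 and 0.0126 (edgeR quasi-likelihood test, line as block).

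Of 23446 genes tested across the 9 lines, 2503 rose and 4170 fell with the combination at an adjusted p under 0.05, against a spread between lines of 13.3% (biological coefficient of variation). Without BT-549 the count was 4318 genes. The excess of falls depended on the lines used: 1901 rose and 2417 fell without BT-549, 2344 and 2850 without MDA-MB-468, and 1930 and 3192 without HCC1937. Without HCC1395 DMSO replicate 3, 2812 rose and 3366 fell. Fitted alone, each of the 9 lines had more risen than fallen genes. The authors assigned each peak to 1 gene, so a gene that shares its promoter with a neighbour can hold only part of its own signal.

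**Figure D1:**
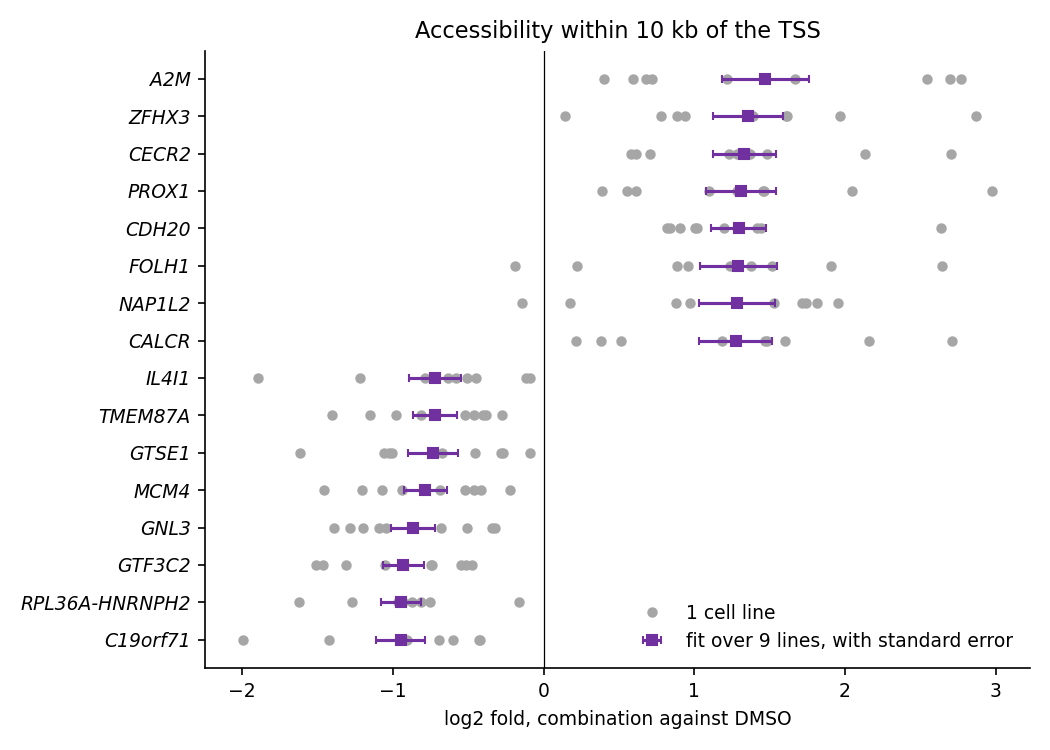
Log2 fold of accessibility within 10 kb of the TSS (x axis, combination against DMSO) for the 8 genes with the largest rise and the 8 with the largest fall by the rule fixed beforehand. Grey points are single cell lines, squares the fit over 9 lines with its standard error. The fitted values run from -0.95 for C19orf71 to 1.47 for A2M, and nearly all lines lie on the same side of 0.

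Developmental genes that PRC2 is known to silence were among those that rose. Of the 59 measured members of this list, 22 rose and 0 fell (27 and 0 adjusted over the list alone). They were led by OTX2, a homeobox factor of forebrain and eye (1.12 ± 0.28), NEUROG2, a proneural factor (0.77 ± 0.20), LHX8 (0.73 ± 0.18) and OLIG2, a factor of oligodendrocytes (0.72 ± 0.18). The list median was 0.25, at the top of 10000 random lists matched on mean accessibility (percentile 100; camera adjusted p = 3.01e-10; adjusted p = 0.280 with an estimated correlation). Its median lay above 0 in each of the 9 lines (0.088 to 0.38), with TMM, size factor and total count scaling alike. With gene windows of 1 kb the lowest was 0.0039, in MDA-MB-231. Markers of endothelial cells, a cell type these cultures should not hold, had 3 risen and 0 fallen members of 15 measured (3 and 0 adjusted over the list alone). These were FLT1 (0.77 ± 0.15), KDR (0.52 ± 0.15) and ERG (0.45 ± 0.14). The median of that list was 0.10 (camera adjusted p = 0.0498; adjusted p = 0.754 with an estimated correlation). Its call was lost with total count scaling, with abundance-trended offsets and with gene windows of 1 kb and 50 kb. Immune cell markers, likewise foreign to the cultures, had 2 risen and 2 fallen members of 17 measured (2 and 2 adjusted over the list alone). CD163 (0.42 ± 0.12) and CSF1R (0.13 ± 0.040) rose, CD68 (-0.19 ± 0.062) and SPI1 (-0.099 ± 0.029) fell. The median was 0.011 (-0.040 with abundance-trended offsets), with a fry direction below 0.

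Cell cycle and replication genes lost accessibility: 0 rose and 17 fell of 30 measured (0 and 20 adjusted over the list alone). Among them were MCM4, CCNE2, a cyclin (-0.42 ± 0.12), BIRC5, survivin (-0.36 ± 0.066), and AURKB, the mitotic kinase (-0.35 ± 0.050). Their median was -0.13 (camera adjusted p = 7.93e-08; adjusted p = 0.520 with an estimated correlation). Housekeeping genes fell as well, with 0 risen and 11 fallen of 14 measured (0 and 13 adjusted over the list alone). Examples are GAPDH (-0.28 ± 0.089), SDHA (-0.24 ± 0.083) and RPL13A (-0.20 ± 0.041). Their median was -0.13 (camera adjusted p = 2.21e-05; adjusted p = 0.520 with an estimated correlation). In each of the 9 lines the medians of both lists lay below 0, from -0.17 to -0.050 and from -0.16 to -0.055. Sterol and fatty acid synthesis genes under SREBP fell too, with 0 risen and 9 fallen of 23 measured (1 and 12 adjusted over the list alone). Among them were SQLE, squalene epoxidase (-0.48 ± 0.13), SREBF1 (-0.18 ± 0.053) and MVK (-0.14 ± 0.037). The median was -0.099 (camera adjusted p = 0.0152; adjusted p = 0.754 with an estimated correlation). The call was lost with abundance-trended offsets, an alternative chosen after the data were examined (median -0.044), and with peaks within 1 kb.

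Of markers of breast cell states, single genes changed with the combination across the 9 lines. The progesterone receptor PGR (0.77 ± 0.11, 9 of 9 lines) rose among luminal markers, while EPCAM (-0.31 ± 0.088) and TSPAN1 (-0.14 ± 0.042) fell. In all, 2 rose and 3 fell of 29 measured members (2 and 3 adjusted over the list alone), with a median of 0.0087. Among basal markers 2 rose and 2 fell of 28 measured members (2 and 1 adjusted over the list alone). MME (0.34 ± 0.092) and NGFR (0.27 ± 0.060) rose, SFN (-0.18 ± 0.036) and ITGA6 (-0.11 ± 0.037) fell. The median was -0.035 (0.012 with abundance-trended offsets). Mesenchymal markers had 2 risen and 0 fallen members of 25 measured (0 and 0 adjusted over the list alone), among them PRRX1 (0.47 ± 0.16). The median was 0.10, the camera adjusted p was 0.0527, and with size factors or abundance-trended offsets the list passed (medians 0.10 and 0.13). For targets of YAP and TEAD, 4 rose and 0 fell of 21 measured members (4 and 0 adjusted over the list alone). These were RBMS3 (0.74 ± 0.20), ANKRD1 (0.40 ± 0.047), CCN2 (0.29 ± 0.072) and FOXF2 (0.20 ± 0.052). The median of 0.0081 became 0.080, past the threshold, with abundance-trended offsets. Receptor tyrosine kinases and adaptors had 2 risen and 4 fallen members of 24 measured (2 and 4 adjusted over the list alone), with FLT3 (0.67 ± 0.17) and ERBB4 (0.30 ± 0.092) up and ERBB2 (-0.22 ± 0.048) and MST1R (-0.15 ± 0.050) down. Their median of 0.037 became 0.082, past the threshold, with the same offsets.

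Pathways read out by AKT inhibition moved little as groups. FOXO target genes, which AKT restrains, had 3 risen and 2 fallen members of 30 measured (1 and 1 adjusted over the list alone). PDK4 (0.38 ± 0.081) and SESN3 (0.23 ± 0.077) rose, while DDIT4 (-0.21 ± 0.038) and CDKN1B, a cell cycle inhibitor (-0.52 ± 0.15), fell. The median was -0.030, turning to 0.027, with a call upwards, with abundance-trended offsets. AP-1, immediate early and ERK feedback genes had 1 risen and 6 fallen members of 28 measured (1 and 6 adjusted over the list alone), including FOSL1 (-0.18 ± 0.059), FOSL2 (-0.14 ± 0.039), DUSP5 (-0.14 ± 0.040) and DUSP4 (-0.13 ± 0.040). The median of -0.034 turned to 0.036, likewise called upwards, with those offsets. In the mammary involution and gp130-STAT3 list 2 rose and 5 fell of 26 measured members (2 and 5 adjusted over the list alone). IGFBP5 (0.38 ± 0.12) and JAK1 (0.18 ± 0.047) rose, CTSD (-0.19 ± 0.045) and OSM (-0.21 ± 0.064) fell, and the median was -0.044. BCL2 family genes had 1 risen and 3 fallen members of 16 measured (1 and 3 adjusted over the list alone). HRK, a pro-apoptotic member, rose (0.36 ± 0.095) and BAX (-0.17 ± 0.042), BID (-0.12 ± 0.036) and BAD (-0.12 ± 0.034) fell. The median was -0.047. Interferon response and antigen presentation genes had 1 risen and 3 fallen members of 19 measured (0 and 1 adjusted over the list alone). CXCL9 (0.31 ± 0.10) rose and ISG15 (-0.34 ± 0.11) and IFIH1 (-0.078 ± 0.024) fell, and the median was -0.036. Among the drug targets and their pathway members 0 rose and 3 fell of 18 measured members (0 and 3 adjusted over the list alone). These were RBBP4, a PRC2 subunit (-0.72 ± 0.16), TSC2 (-0.30 ± 0.091) and KDM6B, a histone demethylase that opposes PRC2 (-0.17 ± 0.034). The median was -0.063 (camera adjusted p = 0.0697; the list passed with peaks within 50 kb). Camera adjusted p for the FOXO, AP-1, involution, BCL2, interferon, immune, luminal, basal, receptor and YAP/TEAD lists lay between 0.201 and 0.947. No list of the 17 passed with an estimated correlation. By fry, which tests the direction of a list against 0 and not against other genes, PRC2 targets, cell cycle, housekeeping, SREBP, endothelial and drug target genes moved one way (adjusted p from 0.00202 to 0.0489).

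**Figure D2:**
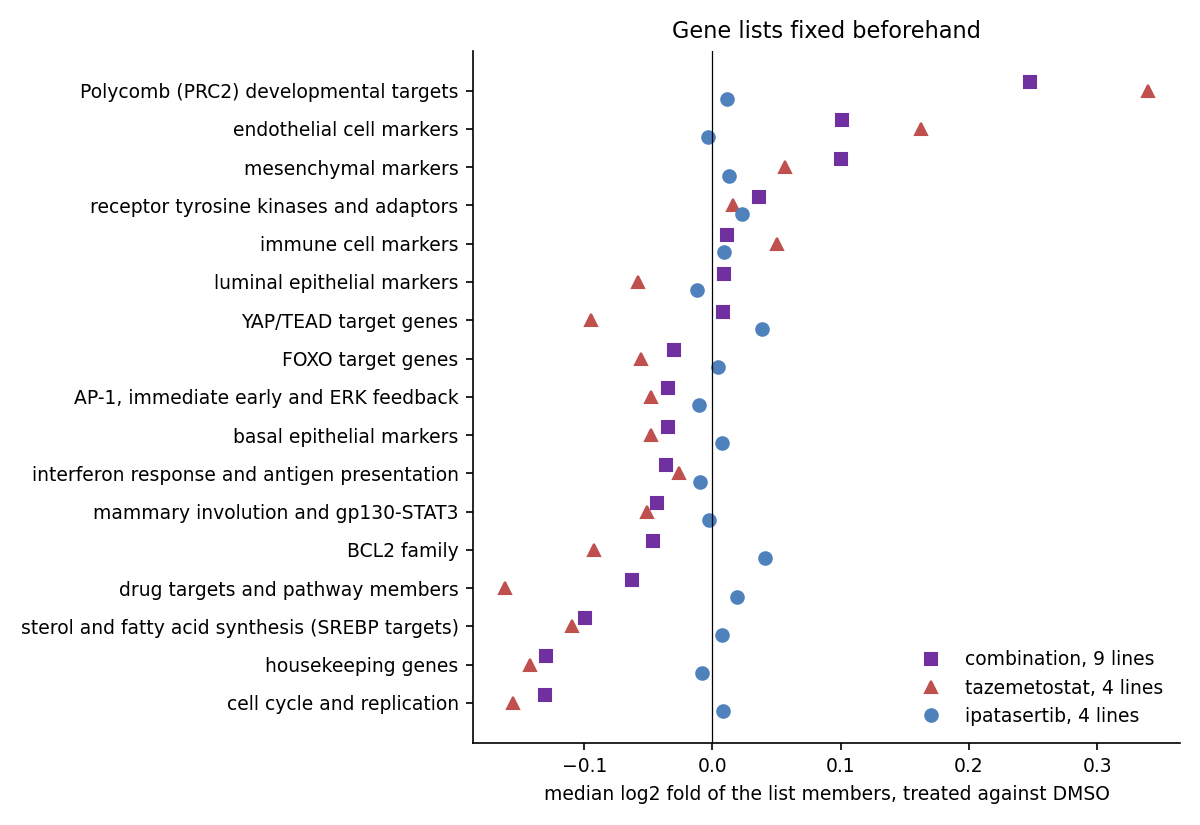
Median log2 fold of accessibility (x axis, treated against DMSO) of the members of each of the 17 gene lists (y axis) for the combination across 9 lines, tazemetostat across 4 lines and ipatasertib across 4 lines. The Polycomb (PRC2) list has the highest median with the combination (0.25) and with tazemetostat (0.34), and lies at 0.011 with ipatasertib. With abundance-trended offsets the FOXO, AP-1 and immune medians change sign for the combination and tazemetostat, as do the basal median for the combination and the luminal median for tazemetostat. Small ipatasertib medians change sign with scaling.

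A panel of lineage and pathway genes was named in advance, and 18 of its 20 members had values. Across the 9 lines 1 of them passed: STAT3, the gp130 effector, fell by 0.11 ± 0.036 (adjusted p = 0.0356, edgeR), in 8 of 9 lines. The luminal factors went in different directions from line to line. By the tests within lines GATA3 rose in 5 lines (0.17 to 0.67) and fell in MDA-MB-231 (-0.28). FOXA1 rose in MDA-MB-231, BT-549 and HCC1395 (0.21 to 0.65) and fell in MDA-MB-468 and HCC1143 (-0.31 to -0.098). ELF3 rose in MDA-MB-231 and BT-549 (0.27 to 0.49) and fell in 5 lines (-0.57 to -0.21). The difference between lines passed for each (F test adjusted p = 5.09e-19, 1.02e-29 and 1.21e-08). The error of that test is the one between replicate libraries, so it covers counting error and not the spread between repeated cultures. Their values across lines were 0.18 ± 0.089, 0.045 ± 0.085 and -0.17 ± 0.097 (adjusted p = 0.145, 0.711 and 0.188). Keratin genes split likewise. KRT8 rose in 4 lines (0.17 to 0.85) and fell in MDA-MB-468 (-0.22). KRT5 rose in BT-549 (0.86) and fell in 6 lines (-0.54 to -0.096). KRT14 rose in BT-549 (0.52) and fell in 4 lines (-0.54 to -0.17). They stood at 0.066 ± 0.097, -0.11 ± 0.11 and -0.13 ± 0.083 across lines. BT-549 gained at KRT5 (0.86 ± 0.078) and KRT8 (0.85 ± 0.14) and lost at VIM (-0.23 ± 0.028), the intermediate filament of mesenchymal cells. TP63 rose in HCC1143 (0.40) and fell in SUM-159PT (-0.17). ZEB1 rose in MDA-MB-468, SUM-149PT and HCC1937 (0.17 to 0.44) and fell in BT-549 (-0.16). VIM rose in MDA-MB-468, SUM-149PT and HCC1143 (0.16 to 0.19) and fell in BT-549 (-0.23). Across lines they stood at -0.073 ± 0.088, 0.067 ± 0.048 and -0.024 ± 0.042. Within lines AKT1, a target of ipatasertib, fell in 4 lines (-0.48 to -0.16). FOXO1 rose in SUM-159PT, BT-549 and HCC1395 (0.17 to 0.29) and FOXO3 fell in SUM-159PT and HCC1143 (-0.11 to -0.083). IRS2 rose in BT-549 (0.57) and fell in MDA-MB-468, HCC1143 and HCC1937 (-0.49 to -0.20), and ERBB3 rose in SUM-159PT (0.14) and fell in MDA-MB-468 (-0.12). BMF, a pro-apoptotic gene, rose in BT-20, HCC1143 and HCC1937 (0.12 to 0.14), and HMGCS1, of sterol synthesis, fell in MDA-MB-468 and HCC1937 (-0.18 to -0.10). Values across lines were -0.17 ± 0.062 for AKT1 (adjusted p = 0.0581), 0.067 ± 0.036 for FOXO1, -0.057 ± 0.024 for FOXO3, -0.073 ± 0.099 for IRS2, -0.035 ± 0.031 for ERBB3, 0.047 ± 0.032 for BMF and -0.079 ± 0.029 for HMGCS1. EZH2 itself stood at -0.030 ± 0.028 (adjusted p = 0.436) and passed in no line with the combination.

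Single peaks (hg38 coordinates) were ranked among 4141 changed peaks. These had a mean log2 CPM of at least 2 and the same direction in at least 8 of the 9 lines. Among them, 2 large rises with the combination across the 9 lines were intergenic. The nearest TSS was that of LOC389602 (chromosome 7, 156064547 to 156065881; 1.70 ± 0.25) or of LEF1-AS1 (chromosome 4, 108360627 to 108362212; 1.62 ± 0.28). The largest fall among the 4141 peaks, -1.26 ± 0.29, was at an intergenic peak 20850 bp from NR4A2, a nuclear receptor (chromosome 2, 156321498 to 156323404). It was followed by exon 4 of 4 of ZNF254, a zinc finger gene (chromosome 19, 24059435 to 24061464; -1.07 ± 0.21), and intron 9 of 11 of RRM2, the regulatory subunit of ribonucleotide reductase (chromosome 2, 10131770 to 10133749; -1.06 ± 0.17). Adjusted p for these peaks ran from 0.00482 to 0.0261 (edgeR). Of 410603 peaks tested, 14488 rose and 11165 fell, 5167 of them by a log2 fold of at least 1. Fallen peaks lay at promoters more often than tested peaks did: 16.9% against 9.03% (odds ratio 2.11), and 11.3% of risen peaks did. Of the lines fitted alone, HCC1395 and BT-20 had the opposite, with 5.73% of fallen against 12.1% of tested peaks (odds ratio 0.403) and 7.53% against 11.9% (0.580). The HCC1395 fit keeps DMSO replicate 3, whose fitted BT-20 share was 10.3%. Its effect on the classes of that line was not tested. Exons held 20.3% of fallen, 8.35% of risen and 11.6% of tested peaks, introns 45.6%, 44.4% and 47.3%. Distal intergenic sites made up 13.1% of fallen peaks, 33.5% of risen peaks and 29.98% of those tested (odds ratio 0.346 for the fallen). Fisher's exact test passed for each of these classes in both directions after adjustment, but neighbouring peaks are not independent. With a filter of 30 counts, chosen after the data were examined, more peaks fell (12448) than rose (8425). With that filter, promoters made up 31.5% of fallen, 16.2% of risen and 14.3% of tested peaks. Without MDA-MB-231 they made up 13.3% of fallen and 12.9% of risen peaks. The shares were 15.3% and 13.7% without MDA-MB-468, and 23.9% and 10.7% without HCC1395. The total of 25653 moved by over 1.5 times without BT-549 (12631), HCC1937 (13359), SUM-159PT (15800), HCC1395 (15907) or MDA-MB-231 (16861).

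Within lines, the extent of the response to the combination differed. MDA-MB-468 changed at 89869 risen and 70652 fallen peaks and SUM-159PT at 76822 risen and 64573 fallen peaks, 56.2% and 52.5% of the peaks tested in each. In the other lines 17.9% to 29.3% changed. In SUM-149PT 27907 rose and 21933 fell, in MDA-MB-231 19756 rose and 17179 fell and in BT-20 22035 rose and 19731 fell. In BT-549 29087 rose and 28812 fell, in HCC1143 29095 rose and 26452 fell, in HCC1395 31923 rose and 29740 fell and in HCC1937 28608 rose and 24711 fell. The HCC1395 fit keeps DMSO replicate 3, with its fitted BT-20 share. Changes of at least 1 on the log2 scale numbered from 12075 in BT-20 to 89687 in MDA-MB-468. These counts measure how many differences exceed counting error. DESeq2 called fewer: 21591 in SUM-149PT, 14554 in MDA-MB-231, 14893 in BT-20, 23704 in BT-549, 23600 in HCC1143, 28321 in HCC1395 and 17356 in HCC1937. With total count scaling the split was 22188 risen to 12193 fallen in MDA-MB-231 and 34749 to 21158 in BT-549. With a filter of 30 counts 73919 peaks passed in MDA-MB-468, 71321 in SUM-159PT, 21316 in MDA-MB-231, 26280 in BT-20, 37682 in BT-549, 34858 in HCC1143 and 39669 in HCC1395.

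**Figure D3:**
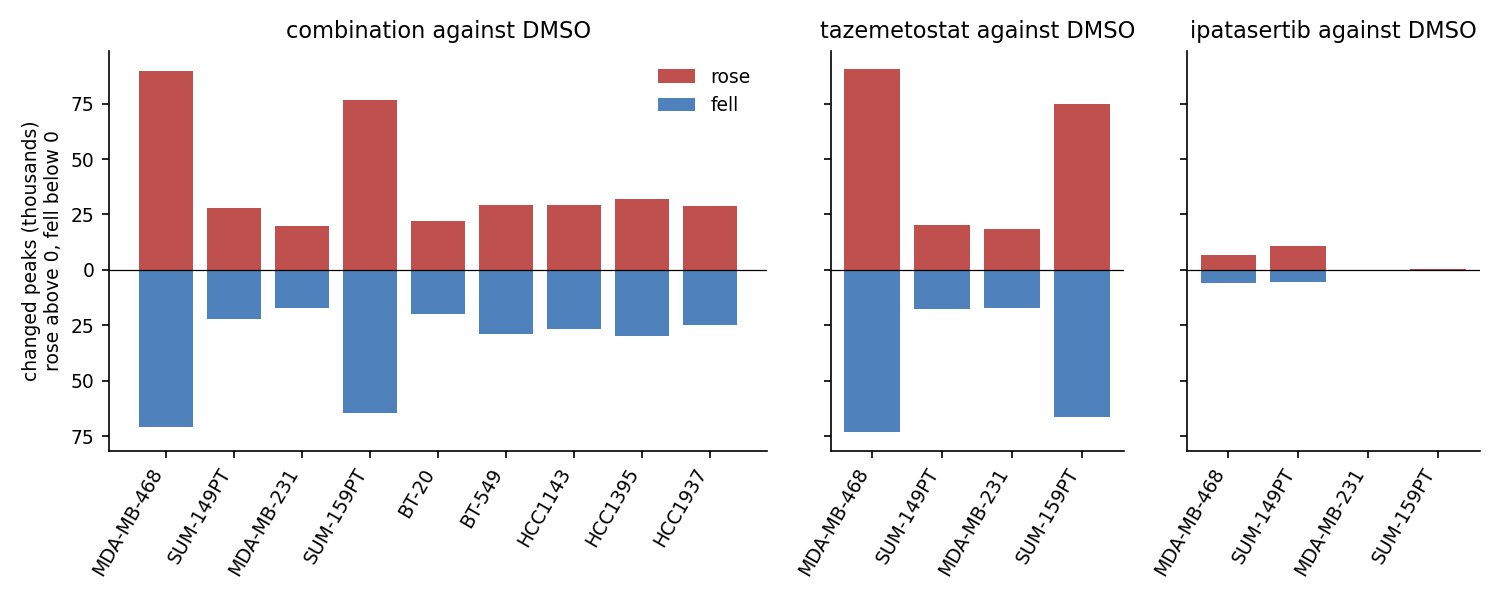
Number of peaks (y axis, in units of 1000) that rose (above 0) or fell (below 0) at an adjusted p under 0.05 in each cell line (x axis), with the combination (9 lines), tazemetostat (4 lines) and ipatasertib (4 lines), each against DMSO. MDA-MB-468 and SUM-159PT have the tallest bars for the combination and tazemetostat. The bars for ipatasertib are short, with 16109 changed peaks in SUM-149PT and 161 in MDA-MB-231.

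The genes with the largest changes in a line also differed between lines. In MDA-MB-468, SSX7, a cancer-testis antigen (3.79 ± 0.24), and SULF1, a heparan sulfatase (3.67 ± 0.23), rose, and the histone gene H4C9 (-3.12 ± 0.15) and GABPB2 (-2.20 ± 0.19) fell. SULF1 was also among the largest rises in BT-20 (2.10 ± 0.21) and HCC1937 (1.67 ± 0.16). SUM-149PT gained at NAP1L3 (2.45 ± 0.19) and TSHZ3 (2.12 ± 0.20) and lost at LIF, a cytokine acting through gp130 (-1.42 ± 0.12), and PCDHGA1, a protocadherin (-1.29 ± 0.19). MDA-MB-231 gained at A2M (2.59 ± 0.12) and RFPL4AL1 (2.46 ± 0.14) and lost at GTF2F1 (-2.41 ± 0.28) and the chaperone gene DNAJA1 (-1.63 ± 0.12). In SUM-159PT, FOCAD (4.05 ± 0.36) and FARP1 (3.67 ± 0.14) rose, while CSE1L (-1.91 ± 0.16) and IL4I1 (-1.86 ± 0.24) fell. BT-20 gained at the olfactory receptor gene OR4Q3 (2.18 ± 0.27) and lost at CDC42SE2 (-1.75 ± 0.25) and ZNF728 (-1.53 ± 0.19). BT-549 gained at NAP1L2 (2.01 ± 0.22) and lost at CHMP5 (-1.04 ± 0.22) and TMEM89 (-1.01 ± 0.18). For HCC1143 the rises were at GOLGA6C (1.78 ± 0.29) and the potassium channel gene KCNJ13 (1.75 ± 0.27), the falls at CRYZ (-2.56 ± 0.23) and PMFBP1 (-1.60 ± 0.16). HCC1395 gained at RAD1 (2.04 ± 0.25) and ADARB2 (2.03 ± 0.14) and lost at MAU2 (-1.79 ± 0.24) and ACTL8 (-1.75 ± 0.15). HCC1937 gained at TMPRSS15, enteropeptidase (1.72 ± 0.17), and lost at RPL36A-HNRNPH2 (-1.64 ± 0.15) and ZIM3 (-1.49 ± 0.25). Values are log2 folds ± SE of the edgeR fit within the line (adjusted p of at most 6.79e-05). SSX7, GOLGA6C, RFPL4AL1, PCDHGA1 and H4C9 have near-identical relatives, so their counts can hold reads of another copy.

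Within lines, single peaks were ranked among changed peaks with a mean log2 CPM of at least 2 and no overlap of replicates. The most changed of these in each line were all distal or intronic. MDA-MB-468 gained at intron 2 of 32 of DGKI (chromosome 7, 137755969 to 137756902; 5.80 ± 0.20) and lost at intron 1 of 4 of ATP1B3 (chromosome 3, 141900074 to 141900973; -3.47 ± 0.15). SUM-149PT gained at intron 4 of 6 of LOC105372156 (chromosome 18, 60674771 to 60675690; 1.97 ± 0.13) and lost at intron 1 of 4 of SCD5 (chromosome 4, 82706392 to 82707309; -1.60 ± 0.12). For MDA-MB-231 the rise lay at intron 2 of 20 of GRAMD1B (chromosome 11, 123517799 to 123520060; 2.45 ± 0.12) and the fall at the intergenic peak near NR4A2 (-2.93 ± 0.39) that also leads the falls across lines. Intergenic peaks near FAM171A1 led the rises in SUM-159PT (chromosome 10, 15485670 to 15486772; 5.64 ± 0.20) and BT-549 (chromosome 10, 15472009 to 15473385; 2.62 ± 0.15). The falls there lay at intron 1 of 16 of CLIP2 (chromosome 7, 74302640 to 74303382; -2.58 ± 0.14) and at an intergenic peak near LINC02070 (chromosome 3, 86577700 to 86578861; -1.61 ± 0.12). BT-20 gained at intron 10 of 21 of DLG2 (chromosome 11, 83864331 to 83866171; 3.43 ± 0.11) and lost at an intergenic peak near ZNF729 (chromosome 19, 22256980 to 22258217; -1.96 ± 0.13). HCC1143 gained at an intergenic peak near NUAK1 (chromosome 12, 105959999 to 105961391; 3.81 ± 0.13) and lost at intron 1 of 4 of LOC105374701 (chromosome 5, 28726556 to 28727380; -2.87 ± 0.15). In HCC1395 the changes lay near LOC105377564 (chromosome 4, 179803664 to 179804958; 3.29 ± 0.11) and near C6orf223 (chromosome 6, 43945496 to 43946335; -2.16 ± 0.16). In HCC1937 they lay near TRPA1 (chromosome 8, 72134122 to 72135012; 2.70 ± 0.15) and near OR1I1 (chromosome 19, 15075601 to 15076369; -1.92 ± 0.12). All are intergenic.

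Tazemetostat alone was tested in the 4 lines that had single agents. Across these lines A2M (2.32 ± 0.35), SSX7 (2.27 ± 0.53), ZFHX3 (2.03 ± 0.31), FOLH1 (2.03 ± 0.41) and LDB2, a LIM domain binding cofactor (1.95 ± 0.38), had the largest rises. The largest falls were those of C19orf71 (-1.23 ± 0.24), HDLBP (-0.80 ± 0.19), GTF3C2 (-0.77 ± 0.18), SF3A1, a splicing factor (-0.77 ± 0.21), and CYB5D2 (-0.74 ± 0.20). Each held in 4 of 4 lines (log2 fold ± SE, n = 4 lines; edgeR adjusted p from 0.00337 to 0.0227). PRC2 developmental targets had 18 risen and 2 fallen members of 60 measured (22 and 3 adjusted over the list alone). Among them were OTX2 (1.84 ± 0.36) and the heart and limb factors TBX20 (1.68 ± 0.48) and TBX5 (1.51 ± 0.52), and GSC (1.22 ± 0.37). Their median was 0.34 (camera adjusted p = 1.33e-05; adjusted p = 0.381 with an estimated correlation). Endothelial markers, foreign to these cultures, had 5 risen and 0 fallen members of 15 measured (5 and 0 adjusted over the list alone). They include FLT1 (0.91 ± 0.26), EMCN (0.83 ± 0.22), TEK (0.76 ± 0.25) and ERG (0.72 ± 0.24). The median was 0.16 (camera adjusted p = 0.0178; adjusted p = 0.381 with an estimated correlation). The call was lost with abundance-trended offsets and with gene windows of 1 kb and 50 kb. Cell cycle genes had 0 risen and 14 fallen members of 30 measured (0 and 18 adjusted over the list alone). Examples are CDT1 (-0.30 ± 0.076), AURKB (-0.23 ± 0.062), CDK2 (-0.21 ± 0.051) and BUB1 (-0.18 ± 0.046). The median was -0.16 (camera adjusted p = 1.27e-04; adjusted p = 0.668 with an estimated correlation). For drug targets and pathway members 0 rose and 5 fell of 18 measured members (0 and 9 adjusted over the list alone). RPS6KB1 (-0.76 ± 0.22), KDM6B (-0.21 ± 0.040), TSC1 (-0.18 ± 0.047) and KDM6A (-0.17 ± 0.032) were among the falls (median -0.16, camera adjusted p = 0.00436; adjusted p = 0.586 with an estimated correlation). Housekeeping genes had 0 risen and 8 fallen members of 14 measured (0 and 9 adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.00156; adjusted p = 0.586 with an estimated correlation). Examples are GAPDH (-0.38 ± 0.13), RPL13A (-0.27 ± 0.042) and PPIA (-0.18 ± 0.045). The calls for drug targets and housekeeping genes were lost with abundance-trended offsets and with peaks within 1 kb.

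No call was made for the remaining 12 lists with tazemetostat (camera adjusted p from 0.0538 to 0.930). Among luminal markers 2 rose and 3 fell of 29 (2 and 3 adjusted over the list alone; median -0.058). PGR (1.08 ± 0.17) rose and XBP1 (-0.17 ± 0.032) and MLPH (-0.17 ± 0.049) fell. The mean and the camera direction lay above 0 and the median below (0.026 with abundance-trended offsets). Among basal markers 0 rose and 2 fell of 28 (0 and 0 adjusted over the list alone; median -0.048), KRT5 (-0.34 ± 0.093) and ITGA6 (-0.14 ± 0.039). Among mesenchymal markers 0 rose and 1 fell of 25 (0 and 0 adjusted over the list alone; median 0.056), S100A4 (-0.19 ± 0.049). FOXO targets had 0 risen and 4 fallen of 30 (0 and 3 adjusted over the list alone; median -0.056). DDIT4 (-0.19 ± 0.042), RBL2 (-0.15 ± 0.050), FOXO3 (-0.12 ± 0.029) and SESN1 (-0.094 ± 0.027) fell. The median turned to 0.028 with abundance-trended offsets. In the involution and gp130-STAT3 list 1 rose and 7 fell of 26 (1 and 7 adjusted over the list alone; median -0.051), its mean lying above 0. CEBPB (-0.31 ± 0.049), OSM (-0.21 ± 0.051), CTSD (-0.20 ± 0.060) and STAT3 (-0.17 ± 0.045) fell. BCL2 family genes had 0 risen and 5 fallen of 16 (0 and 6 adjusted over the list alone; median -0.093). The falls include BAX (-0.28 ± 0.051), BAD (-0.19 ± 0.054), BID (-0.18 ± 0.059) and BCL2L2 (-0.17 ± 0.031). For interferon genes 0 rose and 2 fell of 19 (0 and 1 adjusted over the list alone; median -0.026), among them ISG15 (-0.41 ± 0.068). For SREBP targets 0 rose and 8 fell of 23 (0 and 8 adjusted over the list alone; median -0.11). Among them were FASN (-0.26 ± 0.083), MVK (-0.17 ± 0.059) and MVD (-0.17 ± 0.047). The SREBP list passed with size factors and with peaks within 50 kb. AP-1 and ERK feedback genes had 1 risen and 3 fallen of 28 (1 and 3 adjusted over the list alone; median -0.048). ETV5 rose (0.62 ± 0.18) and FOSL2 (-0.22 ± 0.032), DUSP4 (-0.16 ± 0.030) and SPRED1 (-0.14 ± 0.035) fell. The median turned to 0.036, called upwards, with the same offsets. Receptor kinases had 1 risen and 3 fallen of 24 (1 and 3 adjusted over the list alone; median 0.016). ERBB4 rose (0.32 ± 0.058) and VEGFA (-0.25 ± 0.051), ERBB2 (-0.21 ± 0.052) and IRS1 (-0.094 ± 0.027) fell, with a camera direction below 0. YAP and TEAD targets had 2 risen and 3 fallen of 21 (2 and 3 adjusted over the list alone; median -0.094). RBMS3 (1.06 ± 0.33) and ANKRD1 (0.33 ± 0.067) rose, F3 (-0.15 ± 0.026) and TEAD1 (-0.14 ± 0.044) fell. Immune markers had 1 risen and 0 fallen of 17 (0 and 0 adjusted over the list alone; median 0.050), CD163 (0.61 ± 0.18). The immune median turned to -0.048 with abundance-trended offsets.

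Of 23907 genes tested across the 4 lines, 2358 rose and 4470 fell with tazemetostat. The total of 6828 was 1408 without SUM-159PT, 2387 without MDA-MB-468 and 3573 without SUM-149PT. It was 3792 with abundance-trended offsets or 4272 with peaks within 1 kb. Within lines, 90657 rose and 73264 fell in MDA-MB-468, 74973 rose and 66275 fell in SUM-159PT, 20282 rose and 17681 fell in SUM-149PT and 18582 rose and 17035 fell in MDA-MB-231, counted in peaks. DESeq2 called 14229 peaks in SUM-149PT and 15063 in MDA-MB-231. A filter of 30 counts left 73859, 70812 and 21315 calls in MDA-MB-468, SUM-159PT and MDA-MB-231. With total count scaling the split was 22776 risen to 12588 fallen in SUM-149PT and 21579 to 11096 in MDA-MB-231. The genes with the largest rise in a line were SULF1 (4.04 ± 0.22) and SSX7 (3.80 ± 0.23) in MDA-MB-468 and NAP1L3 (2.29 ± 0.20) and TSHZ3 (2.10 ± 0.20) in SUM-149PT. They were A2M (2.58 ± 0.13) and RFPL4AL1 (2.34 ± 0.14) in MDA-MB-231, and FARP1 (3.69 ± 0.14) and FOCAD (3.66 ± 0.39) in SUM-159PT. These genes also led the combination there. Falls were led by C19orf71 (-1.74 ± 0.14) and ATP6AP1 (-1.48 ± 0.16) in MDA-MB-468 and by RAB2B (-1.31 ± 0.26) and C19orf71 (-1.21 ± 0.19) in SUM-149PT. In MDA-MB-231 they were led by GTF2F1 (-1.85 ± 0.26) and OR52L1 (-1.40 ± 0.24), in SUM-159PT by FAM120A (-1.88 ± 0.22) and IL4I1 (-1.70 ± 0.23). Among panel genes, KRT5 fell in 4 lines (-0.61 to -0.13), and KRT8 rose in MDA-MB-231 (0.24) and fell in MDA-MB-468 and SUM-159PT (-0.56 to -0.46). FOXA1 rose in MDA-MB-231 (0.65) and GATA3 rose in SUM-149PT and SUM-159PT (0.20 to 0.72). ELF3 rose in MDA-MB-231 (0.22) and fell in MDA-MB-468, SUM-149PT and SUM-159PT (-0.32 to -0.11). ZEB1 rose in MDA-MB-468 and SUM-149PT (0.16 to 0.35) and VIM rose in MDA-MB-468 and SUM-149PT (0.14 to 0.17). KRT14 fell in SUM-149PT (-0.34) and AKT1 fell in MDA-MB-468 and SUM-159PT (-0.46 to -0.22). STAT3 fell in MDA-MB-468 and SUM-159PT (-0.23 to -0.21), FOXO1 rose in SUM-159PT (0.28) and FOXO3 fell in SUM-149PT and MDA-MB-231 (-0.13 to -0.12). ERBB3 rose in SUM-159PT (0.15) and fell in MDA-MB-468 and SUM-149PT (-0.14 to -0.12). TP63 fell in SUM-159PT (-0.14), BMF fell in MDA-MB-468 (-0.089) and EZH2 fell in SUM-159PT (-0.14).

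Ipatasertib alone, given for 24 hours, changed fewer peaks than tazemetostat in each of the 4 lines. In MDA-MB-468, GFRAL (1.60 ± 0.16) and NELFCD (1.60 ± 0.21) rose and the histone genes H4C9 (-1.73 ± 0.11) and H1-6 (-1.36 ± 0.10) fell. SUM-149PT gained at RPL4 (0.85 ± 0.18) and ANGPTL1 (0.79 ± 0.25) and lost at CLDN16, a claudin (-1.19 ± 0.24; 0.016 with peaks within 50 kb), and the chemokine gene CCL7 (-1.08 ± 0.23). MDA-MB-231 gained at AMH (0.59 ± 0.12) and PLPPR3 (0.39 ± 0.054) and lost at H1-6 (-0.87 ± 0.18) and RPL36A-HNRNPH2 (-0.74 ± 0.13). In SUM-159PT the potassium channel gene KCNK2 (0.84 ± 0.090) and RCN1 (0.68 ± 0.18) rose. ARV1 (-0.91 ± 0.24) and PTGS2, cyclooxygenase (-0.86 ± 0.22), fell (edgeR within lines, adjusted p of at most 0.0429). Of the panel, ELF3 fell in MDA-MB-468 and SUM-149PT (-0.30 to -0.085), KRT14 rose in MDA-MB-468 (0.16), KRT5 fell in SUM-149PT (-0.15) and KRT8 rose in MDA-MB-468 (0.20). By peaks, 10593 rose and 5516 fell in SUM-149PT, 6747 rose and 5863 fell in MDA-MB-468, 493 rose and 395 fell in SUM-159PT and 23 rose and 138 fell in MDA-MB-231.

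Across the 4 lines edgeR called 0 of 23907 genes with ipatasertib (537 at an unadjusted p under 0.05). DESeq2 called 0. On simulated data for this comparison, 44% of genes changed 1.5-fold and 1% of genes changed 1.2-fold were recovered. Smaller shared changes were thus not detectable. No member of the 17 lists passed over all genes, and adjusted over the list alone 1 rose and 1 fell in the involution and gp130-STAT3 list. List medians lay between -0.012 and 0.041 (camera adjusted p from 0.0970 to 0.942). That of PRC2 targets was 0.011 and that of FOXO targets 0.0046 (with total count scaling -0.0026 and -0.0081). The YAP/TEAD list, at 0.039, passed with peaks within 50 kb. The members with the largest values, such as KRT6C (-0.72 ± 0.21), WT1 (-0.59 ± 0.30), LIF (-0.29 ± 0.19) and CDC20 (0.32 ± 0.13), did not pass. In SUM-159PT 506 peaks passed without a filter. DESeq2 called 3343, 4530, 72 and 17 peaks in SUM-149PT, MDA-MB-468, SUM-159PT and MDA-MB-231. Leaving out 1 library gave 8000 to 8295 in MDA-MB-468 (without DMSO replicate 1 or 3 or ipatasertib replicate 1 or 3) and 7368 to 9909 in SUM-149PT (without DMSO replicate 3 or ipatasertib replicate 2 or 3). It gave 57 to 244 in MDA-MB-231 (without DMSO replicate 1, 2 or 3 or ipatasertib replicate 2 or 3) and 247 to 576 in SUM-159PT (without any 1 of its libraries). The split depended on the scaling. With size factors 10958 rose and 4417 fell in MDA-MB-468 and 647 and 330 in SUM-159PT. In SUM-149PT the numbers were 6449 and 6543 with total counts, 5071 and 4681 with abundance-trended offsets.

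What each agent added to the other was compared next. In the same 4 lines the combination against DMSO raised 1761 and lowered 2991 genes (468 changed without SUM-159PT, 1805 without MDA-MB-468 and 2638 without SUM-149PT, against 4752). The excess of falls was small or absent when either of 2 lines was left out: 238 rose and 230 fell without SUM-159PT, and 875 and 930 without MDA-MB-468. PRC2 targets had 17 risen and 0 fallen members of 60 measured (24 and 0 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 3.33e-07; adjusted p = 0.265 with an estimated correlation). Adding ipatasertib to tazemetostat changed 0 genes across the lines by edgeR (1038 at an unadjusted p under 0.05) and 2 by DESeq2. No member of the 17 lists passed there, over all genes or adjusted over the list alone. List medians lay between -0.048 and 0.060, the highest being that of YAP and TEAD targets (camera adjusted p = 8.22e-04; adjusted p = 0.915 with an estimated correlation). Adding tazemetostat to ipatasertib raised 2093 and lowered 3680 genes, but 266 rose and 225 fell without SUM-159PT, and 818 and 843 without MDA-MB-468. PRC2 targets had 19 risen and 1 fallen members of 60 measured (23 and 1 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 1.92e-06; adjusted p = 0.378 with an estimated correlation). Cell cycle genes had 0 risen and 16 fallen members of 30 measured (0 and 19 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 1.81e-05; adjusted p = 0.551 with an estimated correlation). Endothelial markers (0.18), SREBP targets (-0.098), drug targets (-0.13) and housekeeping genes (-0.13), here by their medians, passed too (camera adjusted p from 0.00198 to 0.0393). None of them passed with an estimated correlation (adjusted p from 0.378 to 0.847). That total of 5773 was 491 without SUM-159PT, 1661 without MDA-MB-468 and 2810 without SUM-149PT. It was 3376 with abundance-trended offsets and 3781 with peaks within 1 kb. A non-additive response, the departure of the combination from the sum of both log2 folds, was called for 0 genes by edgeR (63 at an unadjusted p under 0.05) and 0 by DESeq2. Recovery was not simulated for this contrast or for the combination against tazemetostat. In the simulation of ipatasertib against DMSO in these lines, 44% of 1.5-fold and 1% of 1.2-fold changes were recovered. A call of 0 genes therefore does not show that the effects add up.

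Within lines, the combination differed from tazemetostat at 24660 peaks in MDA-MB-468 (16143 rose and 8517 fell), 15690 in SUM-149PT (9216 rose and 6474 fell), 8667 in SUM-159PT (5266 rose and 3401 fell) and 147 in MDA-MB-231 (85 rose and 62 fell). It differed from ipatasertib at 156422 peaks in MDA-MB-468, 35407 in SUM-149PT (18519 rose and 16888 fell), 144048 in SUM-159PT and 31489 in MDA-MB-231. Non-additive peaks numbered 100 in MDA-MB-468, 18 in MDA-MB-231, 6 in SUM-159PT and 0 in SUM-149PT. By DESeq2 they numbered 4, 1, 0 and 0. In MDA-MB-468, 90 of the non-additive peaks lay above 0 and 10 below. The numbers were 16 and 9 with total counts, 10 and 9 with abundance-trended offsets. In all they were 56 with size factors and 180 without a filter. MDA-MB-231 had 11 with total counts, SUM-159PT 1 with abundance-trended offsets and 2 without a filter. Leaving out 1 library gave 8 to 64 in MDA-MB-468 (without combination replicate 1, 2 or 3, DMSO replicate 2 or 3, ipatasertib replicate 1, 2 or 3 or tazemetostat replicate 1 or 3). It gave 9 to 39 in MDA-MB-231 (without combination replicate 1 or 2, DMSO replicate 2 or 3, ipatasertib replicate 3 or tazemetostat replicate 2 or 3). It gave 0 to 3 in SUM-159PT (without ipatasertib replicate 1 or 3, combination replicate 1 or 3, DMSO replicate 2 or 3 or tazemetostat replicate 2). Against tazemetostat DESeq2 called 10548, 2999, 2149 and 16 peaks. Against ipatasertib it called 12376 in SUM-149PT and 11411 in MDA-MB-231. Without a filter 5528 peaks differed from tazemetostat in SUM-159PT. With a filter of 30 counts 66671, 71960 and 17419 differed from ipatasertib in MDA-MB-468, SUM-159PT and MDA-MB-231. Leaving out 1 library gave, against tazemetostat, 13916 to 15895 in MDA-MB-468 (without combination replicate 2 or 3 or tazemetostat replicate 1 or 3) and 7985 to 10240 in SUM-149PT (without combination replicate 1 or 3 or tazemetostat replicate 1 or 2). It gave 26 to 306 in MDA-MB-231 (without combination replicate 2 or 3 or tazemetostat replicate 1, 2 or 3) and 4419 to 5500 in SUM-159PT (without any 1 of its libraries). Against ipatasertib it gave 22919 in SUM-149PT (without ipatasertib replicate 2). The split against tazemetostat depended on the scaling, with 11139 risen to 10111 fallen in MDA-MB-468 and 6402 to 7496 in SUM-149PT by total counts. It was 8455 to 8297 in MDA-MB-468, 3600 to 4140 in SUM-159PT and 66 to 73 in MDA-MB-231 with abundance-trended offsets. Against ipatasertib it was 20917 to 10344 by total counts and 16600 to 8676 with abundance-trended offsets in SUM-149PT.

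Gene by gene, the combination was then set against each single agent in the 4 lines. The log2 folds of tazemetostat and of the combination, each against DMSO, correlated across genes with r = 0.964 in MDA-MB-468, 0.968 in SUM-159PT, 0.915 in MDA-MB-231 and 0.843 in SUM-149PT. Both comparisons use the same DMSO libraries. Unchanged groups simulated against them gave r = 0.476 to 0.494. The covariance was 0.392 in MDA-MB-468 against 0.00616 simulated, 0.355 against 0.00740 in SUM-159PT, 0.0749 against 0.00611 in MDA-MB-231 and 0.0603 against 0.00497 in SUM-149PT. In MDA-MB-468, 4215 genes rose with both, where independent lists would share 1240. In the same line 3610 fell with both, against 1433. Ipatasertib and the combination correlated with r = -0.0788 in MDA-MB-468, 0.0766 in SUM-159PT, 0.249 in MDA-MB-231 and 0.287 in SUM-149PT. Unchanged groups simulated for this comparison gave r = 0.477 to 0.502. That r is no chance level for the real data, since wide changes with the combination lower r but not the covariance. The covariance of ipatasertib and the combination lay above the simulated one by 0.00739 in SUM-149PT and 0.00198 in MDA-MB-231. It differed from the simulated one by -8.08e-04 in SUM-159PT and -0.0146 in MDA-MB-468. Groups of 3 leave too few DMSO libraries to split, so part of any overlap can come from the shared controls, and genes are not independent replicates.

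Whether the combination acts alike in different lines was tested directly. A2M ranged from 0.40 ± 0.096 in HCC1143 to 2.85 ± 0.092 in SUM-159PT (difference between lines, edgeR F test adjusted p = 1.62e-39). PGR ranged from 0.45 ± 0.11 in HCC1937 to 1.57 ± 0.12 in MDA-MB-468 (adjusted p = 2.68e-08). The response differed between lines for 17455 of 23674 genes. The error of this test is that between replicate libraries. With peaks within 1 kb the count was 9066. Across 18769 genes tested in every line, the log2 folds of 2 lines correlated with r = 0.186 to 0.525 over 36 pairs of lines (median 0.374). The highest was between SUM-159PT and BT-549 (Spearman's rho 0.541, covariance 0.0921) and the lowest between MDA-MB-231 and BT-20 (rho 0.195, covariance 0.0117). The lines have separate controls, and these are correlations across genes, which are not independent replicates.

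Promoters, taken as peaks within 1 kb of a TSS, held 24.8% of counts with DMSO and 23.7% with the combination (means of 9 lines). The share was lower in 7 of 9 lines, the difference being -1.13 ± 1.30 percentage points (SD over lines; exact sign-flip test, 2-sided, p = 0.0430, adjusted p = 0.188 over 12 tests). It did not pass the adjustment. It went from 26.01% to 23.2% in MDA-MB-468 and from 22.7% to 20.1% in SUM-159PT. It went from 23.2% to 24.03% in HCC1395 and from 22.6% to 22.9% in BT-20. HCC1395 DMSO here includes replicate 3, with its fitted BT-20 share. With tazemetostat the mean was 21.99% against 24.8% with DMSO, lower in 4 of 4 lines. With ipatasertib it was 25.03%, higher in 3 of 4. The smallest p an exact test of 4 lines allows is 0.125, which tazemetostat reached (ipatasertib p = 0.375).

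**Figure D4:**
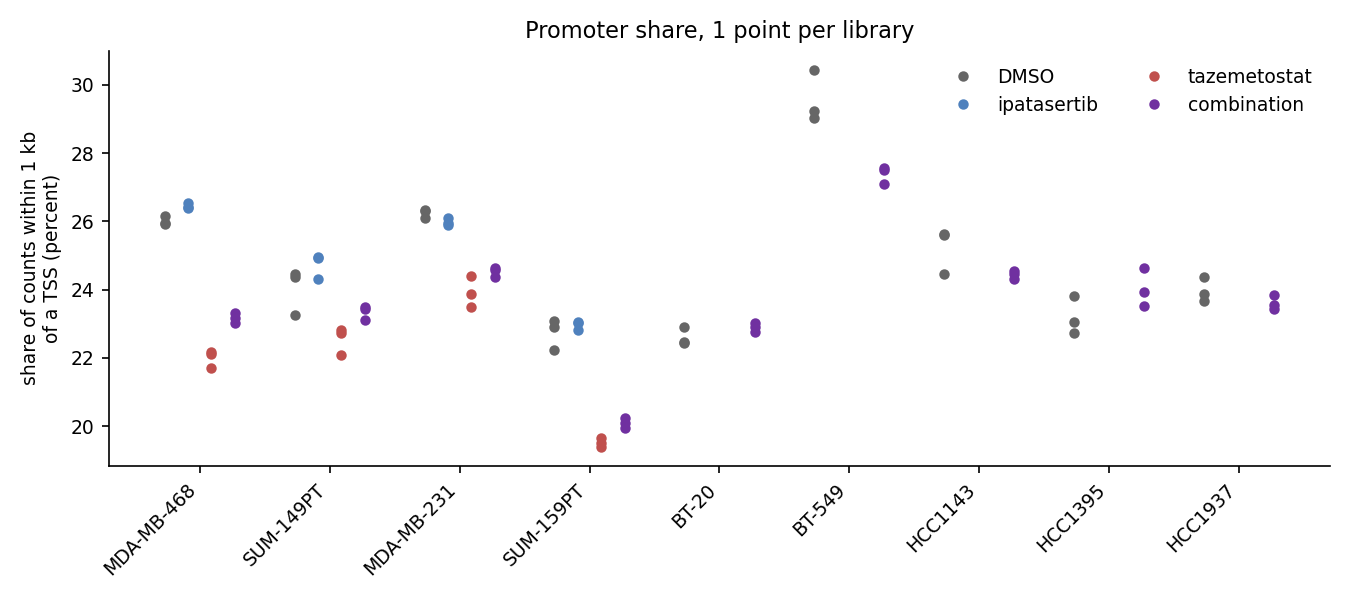
Share of counts within 1 kb of a TSS (y axis, percent) in each library, by cell line (x axis) and treatment (colour). Each point is 1 library and each group has 3. With tazemetostat the points lie below those of DMSO in MDA-MB-468, where the means are 21.99% and 26.01%, and in SUM-159PT, where they are 19.5% and 22.7%.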

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

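No test in this part was chosen only after its result was seen. The interferon response and antigen presentation list had a median log2 fold of 0.11 with the combination in BT-549, where the next highest line had -0.014 and the median of the 9 lines was -0.055. The gap passed Dixon's test for an outlying value. It was the only one of 54 sets of lines to do so, and chance alone gives about 5% of sets. The response to the combination differed between lines for 17455 of 23674 genes by a test of the difference itself. Among 3000 random genes, the real split gave 2199 such genes and the highest of the others 980; 1 of 50 splits, the real one, gave as many. These splits move libraries within lines and cover counting error only, so they leave open chance between cultures. The error of that test is the spread between replicate libraries, which lies below sampling noise, so the count says little of how far lines would differ in repeated cultures.

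Of PRC2 targets, 22 of 59 rose and 0 fell with the combination, and 18 of 60 rose and 2 fell with tazemetostat. As a group they were called with the preset correlation but not with an estimated one (camera adjusted p = 0.280 with the combination and 0.381 with tazemetostat). The promoter share of counts was lower in 7 of 9 lines with the combination and in 4 of 4 with tazemetostat, neither passing adjustment (adjusted p = 0.188 for both). A lower signal over background in the treated libraries would lower strong sites and lift weak ones. Some values go that way. The share of counts in the 20000 strongest peaks changed by -2.16 percentage points with the combination (lower in 7 of 9 lines; exact p = 0.0352, adjusted p = 0.188) and by -4.92 with tazemetostat (lower in 4 of 4). Of 5 equal classes of peaks by mean accessibility, 49.4% of the weakest rose and 69.4% of the strongest fell with tazemetostat in MDA-MB-468, the most marked case. With the combination more of the strongest class rose than fell in HCC1395 (21.8% and 12.2%), BT-20 (12.99% and 10.1%) and SUM-149PT (16.2% and 13.3%). Across 9 lines 3.57% of that class rose and 4.60% fell. Promoter peaks lay below distal peaks of the same strength and width, the mean difference in log2 being -0.051 ± 0.052 (SD over lines, combination against DMSO; lower in 7 of 9 lines, exact 2-sided sign-flip p = 0.0234), against -0.16 unmatched, which argues against a background change as the whole of the promoter difference with the combination, though it may make up part of it. With tazemetostat alone this was not tested. In BT-20 and HCC1395 the matched difference was 0.016 and 0.015. For the PRC2 list, whose median stood at percentile 100 of random lists of equal accessibility, this argues against the same explanation only as far as lists that ignore the correlation between genes can show. The list median stood at percentile 73.3 with ipatasertib alone and 100 with tazemetostat alone, consistent with the hypothesis that EZH2 inhibition, whichever agent it is given with, opens these genes. The longer exposure to tazemetostat stays open as an alternative that this design cannot separate.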

How the results depend on the processing

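Chosen only after the data were seen were the abundance-trended offsets for genes, lists and peaks across lines, the filter of 30 counts across lines, the fits without HCC1395 DMSO replicate 3, the promoter shares with a line or replicate left out and the agreement between lines at other gene windows. By DESeq2 the combination changed 21591 peaks in SUM-149PT, 14554 in MDA-MB-231, 14893 in BT-20, 23704 in BT-549, 23600 in HCC1143, 28321 in HCC1395 and 17356 in HCC1937. By DESeq2 tazemetostat changed 14229 peaks in SUM-149PT and 15063 in MDA-MB-231. By DESeq2 ipatasertib changed 4530 peaks in MDA-MB-468, 3343 in SUM-149PT, 17 in MDA-MB-231 and 72 in SUM-159PT. By DESeq2 the combination against tazemetostat gave 10548 peaks in MDA-MB-468, 2999 in SUM-149PT, 16 in MDA-MB-231 and 2149 in SUM-159PT. By DESeq2 the combination against ipatasertib gave 12376 peaks in SUM-149PT and 11411 in MDA-MB-231. By DESeq2 the non-additive response gave 4 peaks in MDA-MB-468, 1 in MDA-MB-231 and 0 in SUM-159PT. These counts are all lower than in the fits reported. Across lines, DESeq2 called 2 genes for the combination against tazemetostat. With a filter of 30 counts, the combination changed 73919 peaks in MDA-MB-468, 21316 in MDA-MB-231, 71321 in SUM-159PT, 26280 in BT-20, 37682 in BT-549, 34858 in HCC1143 and 39669 in HCC1395. With that filter, tazemetostat changed 73859 peaks in MDA-MB-468, 21315 in MDA-MB-231 and 70812 in SUM-159PT. With that filter, the combination against ipatasertib gave 66671 peaks in MDA-MB-468, 17419 in MDA-MB-231 and 71960 in SUM-159PT, from a smaller number of tested peaks. Without a filter, ipatasertib changed 506 peaks in SUM-159PT, and the combination against tazemetostat gave 5528 peaks in SUM-159PT, and the non-additive response gave 180 peaks in MDA-MB-468 and 2 in SUM-159PT. With size factors, the non-additive response gave 56 peaks in MDA-MB-468; with total counts, the non-additive response gave 25 peaks in MDA-MB-468 and 11 in MDA-MB-231. With abundance-trended offsets, ipatasertib changed 9752 peaks in SUM-149PT, and the non-additive response gave 19 peaks in MDA-MB-468 and 1 in SUM-159PT. Abundance-trended offsets also gave 3792 genes with tazemetostat and 3376 for the combination against ipatasertib across lines, and peaks within 1 kb 4272, 3781 and, for differences between lines, 9066.

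Of the gene lists called across lines with the preset correlation, none was called with an estimated one, at the same medians. Those with the combination across 9 lines and with tazemetostat were PRC2 targets (0.25), cell cycle genes (-0.13), SREBP targets (-0.099), endothelial markers (0.10) and housekeeping genes (-0.13) with the combination, and PRC2 targets (0.34), cell cycle genes (-0.16), endothelial markers (0.16), drug targets (-0.16) and housekeeping genes (-0.14) with tazemetostat. Abundance-trended offsets turned the medians of FOXO targets (0.027) and AP-1 and ERK feedback genes (0.036) with the combination, and AP-1 and ERK feedback genes (0.036) with tazemetostat. With them calls were lost for SREBP targets (-0.044) and endothelial markers (0.095) with the combination, and endothelial markers (0.21), drug targets (-0.094) and housekeeping genes (-0.067) with tazemetostat. They were gained for mesenchymal markers (0.13), receptor kinases (0.082) and YAP/TEAD targets (0.080) with the combination. With peaks within 1 kb calls were lost for SREBP targets (-0.060) and endothelial markers (0.12) with the combination, and endothelial markers (0.21), drug targets (-0.071) and housekeeping genes (-0.078) with tazemetostat. With peaks within 50 kb they were lost for endothelial markers (0.080) with the combination, and endothelial markers (0.16) with tazemetostat and gained for drug targets (-0.10) with the combination, and SREBP targets (-0.11) with tazemetostat, and YAP/TEAD targets (0.026) with ipatasertib. Total counts ended the call of endothelial markers (0.12) with the combination, and size factors made one of mesenchymal markers (0.10) with the combination, and SREBP targets (-0.12) with tazemetostat. The value of CLDN16 with ipatasertib in SUM-149PT became 0.016 with peaks within 50 kb, which adds peaks to the sum. Apart from filters and windows, which change the peaks used, the cause was not tested.

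Leaving out 1 line or replicate gave 4318 to 6511 genes and 12631 to 22338 peaks with the combination across 9 lines. Across 4 lines it gave 468 to 5547 genes with the combination, 1408 to 7464 with tazemetostat and 491 to 6129 for the combination against ipatasertib. Within lines, leaving out 1 library gave 8000 to 8781 in MDA-MB-468, 7368 to 13222 in SUM-149PT, 57 to 244 in MDA-MB-231 and 247 to 576 in SUM-159PT with ipatasertib. It gave 13916 to 19304 in MDA-MB-468, 7985 to 11701 in SUM-149PT, 26 to 306 in MDA-MB-231 and 4419 to 5500 in SUM-159PT for the combination against tazemetostat. It gave 22919 to 27638 in SUM-149PT for the combination against ipatasertib. It gave 8 to 96 in MDA-MB-468, 9 to 39 in MDA-MB-231 and 0 to 6 in SUM-159PT for the non-additive response. Counts fall with fewer libraries, and the cause of rises was not tested. The promoter share difference of the combination ran from -1.37 to -0.910 percentage points, its unadjusted p missing the threshold in 8 of 12 such fits (highest 0.0859). Without HCC1395 DMSO replicate 3 the counts across 9 lines were 6178 genes and 26179 peaks, and 17365 genes differed between lines. The median correlation between lines, 0.374, lay between 0.356 and 0.413 in 4 alternatives. Of all alternatives, 328 of 440 values of peak counts and 108 of 125 of gene counts stayed within 1.5 times the value reported. Of named genes, 3277 of 3898 values stayed, 601 were weaker, 19 stronger and 1 reversed (CLDN16). Of gene lists 272 of 306 stayed, 23 were weaker, 8 stronger and 3 reversed. Stayed means called or not called in both fits. A list counts as reversed when its tested direction turned and either fit called it, so a median that changed sign without a call is not counted. Of named peaks 334 of 336 stayed and 2 were weaker.

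Replicate numbers did not pair the libraries: over the 9 lines the correlations of deviations from the group means for libraries of the same number were at most 0.104, and 1 of 87 pairs exceeded 0.1. With the replicate number within line as a block on single libraries, 12862 genes passed across 9 lines in place of 6673, since the error is then that between libraries and not between lines. Within lines the block changed no count by over 1.5 times. Of genes changed 1.2-fold, 11% were recovered in simulations of the 9 lines; the cause was not tested. Motif analysis was not run.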

Other observations

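The tests on HCC1395 DMSO replicate 3 and on the spread between replicates were chosen only after the result was seen. Lists of cell state markers moved in different directions in different lines with the combination. Of luminal markers, 14 of 29 rose and 1 fell in BT-549 (14 and 1 adjusted over the list alone; median 0.21) and 13 of 29 rose and 2 fell in MDA-MB-231 (14 and 3 adjusted over the list alone; median 0.17). By contrast, 4 of 29 rose and 13 fell in MDA-MB-468 (4 and 13 adjusted over the list alone; median -0.098). Among mesenchymal markers, 18 of 25 rose and 2 fell in HCC1143 (18 and 2 adjusted over the list alone; median 0.22) and 16 of 25 rose and 4 fell in MDA-MB-468 (16 and 4 adjusted over the list alone; median 0.27). Further, 12 of 25 rose and 0 fell in HCC1937 (12 and 0 adjusted over the list alone; median 0.14). By contrast, 3 of 25 rose and 13 fell in SUM-159PT (3 and 13 adjusted over the list alone; median -0.11). For basal markers, 4 of 28 rose and 15 fell in HCC1143 (5 and 15 adjusted over the list alone; median -0.14) and 2 of 28 rose and 12 fell in SUM-149PT (2 and 15 adjusted over the list alone; median -0.12). By contrast, 11 of 27 rose and 2 fell in BT-549 (11 and 2 adjusted over the list alone; median 0.11). Camera adjusted p within lines was 0.00187 to 0.0661 for the luminal, 1.85e-04 to 0.101 for the mesenchymal and 0.00119 to 0.0395 for the basal values. None passed with an estimated correlation (adjusted p from 0.0676). The difference of a list between lines was not tested. PRC2 targets rose in 12 of 55 measured members in MDA-MB-231 and in 40 of 58 in HCC1395, and at most 3 fell in any line (11 and 47 rose adjusted over the list alone).

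HCC1395 DMSO replicate 3 stood apart from replicates 1 and 2. Fitted as a mixture of the DMSO profiles of the other 8 lines, it held 10.3% of BT-20, which is consistent with BT-20 material in that library. The highest share of another line was 1.74% (BT-549). Fitted with 1 source line at a time, the share was 14.5% for BT-20 but also 9.79% for HCC1937, 7.82% for MDA-MB-468, 7.68% for SUM-149PT and 5.89% for HCC1143. A general loss of quality or another state of the cells is therefore left open. Whether cells or library material were mixed stays open, and no biological explanation was tested.

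Replicate libraries differed by less than sampling noise in 76 of 78 pairs. In narrow peaks the ratio of observed to sampling variance was 0.664 and in broad peaks of equal count 0.753 (difference -0.083; lower in 78 of 78 pairs), consistent with the removal of duplicate fragments, which may saturate counts at dense sites. Reads shared by several replicates would lower the ratio at every depth, but it was 0.955 at 20 to 40 counts and 0.633 in the class of highest counts, which argues against them. A shared culture keeps sampling noise and cannot put the ratio below 1. No biological cause was tested.

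For the combination across 9 lines, 1 of 100 splits of treated and control within lines, the real one, called as many of 5000 random genes (1477; highest other 584). Likewise 1 of 100 called as many of 5000 random peaks (295; highest other 6). A share of 1 in 100 makes chance unlikely for both counts, but it does not show which genes or peaks are real. Across 4 lines the 8 possible splits are too few for a share under 0.05. The real counts were 1492 genes with tazemetostat, 1018 with the combination and 1199 for the combination against ipatasertib, with 0 in every other split. All 8 splits gave 0 for ipatasertib and for the combination against tazemetostat. Within lines the 10 splits of 6 libraries are likewise too few. Over 25 comparisons the real counts among 10000 random peaks ran from 9 to 5803, and the highest other was 0 except for the combination against tazemetostat in MDA-MB-231 (9 against 6). For the non-additive peaks of MDA-MB-468, 1 of 30 splits gave as many (5; highest other 0). These splits move libraries of 1 line and cover counting error only, so they leave open chance between cultures. They also break up the response to each agent, so they do not test the non-additive part by itself. Chance cannot be excluded in MDA-MB-231 (3 of 30 splits; 1 real, highest other 194), SUM-149PT (30 of 30; 0 real, highest other 321) or SUM-159PT (30 of 30; 0 real, highest other 0), nor for non-additive genes across lines (30 of 30; 0 real, highest other 1). Splits with far more calls than the real one, in MDA-MB-231 and SUM-149PT, may set libraries with tazemetostat against those without, so that the response to 1 agent passes for a non-additive one.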
